A study of Homo sapiens with 12 samples.

How the data were processed

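Gene expression was measured with Affymetrix Human Exon 1.0 ST arrays in 12 samples of total RNA from established breast cancer cell lines. The labels give 3 arrays for each of 4 groups: MCF-7 with calcitriol at 40 µM, MCF-7 with 0.20% DMSO, MDA-MB-231 with calcitriol at 50 µM and MDA-MB-231 with 0.25% DMSO, each for 24 hours. Calcitriol is the hormonally active form of vitamin D, and DMSO is the solvent of the control arrays. The labels give no DMSO percent for the calcitriol arrays. The arrays were grouped by these labels, and 0 arrays were left out.

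The deposited values are log2 expression values per probeset (a small group of probes for 1 exonic region), with 1432143 probesets on each array. The authors name RMA, Partek and Affymetrix Expression Console 1.3.1.187 for the processing, without the role or order of each. RMA corrects background, normalizes between arrays and summarizes probes. The genome build and the annotation release of the platform are not given in the sources used here, so no coordinates are printed. The median over all probesets lay between 3.79 and 3.86 log2 on the 12 arrays. A set of 20744 probesets read exactly 0 on every array, and 0 of them named a gene in the annotation.

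The annotation held with the data listed 372926 probesets, of which 357604 named 1 gene symbol and 15322 named several, and the other 1059217 probesets of the arrays were not listed in it. Symbols are printed as the annotation gives them: EFTUD1 is now EFL1, SDPR is CAVIN2, GPR56 is ADGRG1, IL8 is CXCL8, SC4MOL is MSMO1, CYR61 is CCN1, RBM35B is ESRP2, and AARS, CARS, WARS and YARS now end in 1. A gene's value on an array was the median log2 value over its probesets, using probesets that named that gene alone and whose mean over the 12 arrays lay above the median of all probesets' means (3.82 log2). Genes with at least 3 such probesets were tested, which gave 16995 genes from 264880 probesets, with a median of 13 probesets per gene. The array medians of these gene values lay between 6.21 and 6.45 log2. Probesets tied to several genes were left out, because they cannot be assigned to 1 gene.

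A linear model with the 4 group means was fitted to all 12 arrays in limma 3.58.1 under R 4.3.3 (with the data.table package, 1.17.8), with empirical Bayes moderation at its default settings. It had 8 residual degrees of freedom and 9.47 prior degrees of freedom. The contrasts were calcitriol minus DMSO in each line, the difference between these effects (MDA-MB-231 minus MCF-7), and MDA-MB-231 minus MCF-7 in DMSO. Tests were two-sided, and p values were adjusted by the Benjamini-Hochberg method over the 16995 genes. A gene was called at an adjusted p under 0.05. Calls in the same direction in both lines were set beside the number that independent lists would share and tested with Fisher's exact test over the genes, which are not independent replicates. The effects in the lines were correlated across genes. Every adjusted p for a gene is limma's, and every adjusted p for a gene list is from camera in limma unless fry is named.

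A set of 21 gene lists was fixed before the data were examined. They were vitamin D receptor targets, the PERK-ATF4 branch of the unfolded protein response, aminoacyl-tRNA synthetases, ATF6-XBP1 chaperone and ERAD genes, cholesterol biosynthesis and uptake, liver X receptor targets, DNA replication and mitosis, the NRF2 antioxidant response, the cytosolic heat shock response, p53 targets, apoptosis regulators, estrogen response, hypoxia and glycolysis, autophagy, NF-kB inflammatory genes, interferon-stimulated genes, immediate early and MAPK feedback genes, cytosolic ribosomal proteins, luminal epithelial markers, mesenchymal and basal-like line markers, and markers of fibroblasts, leukocytes and endothelium. Each list was tested against all other genes with camera at a preset inter-gene correlation of 0.01, adjusted over the 21 lists, and again with the correlation estimated from the arrays. A further planned test, fry in limma, asked of each list by itself, without the other genes, whether its members shifted. It was adjusted over the 21 lists and run in the main setting only. Because camera compares a list with the other genes, its direction can differ from the sign of the list's own median. Members past the threshold were counted over all genes and adjusted over the list alone. Some genes stand on more than 1 list.

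The rule for named genes was fixed before the data were examined. Per line it takes VDR and CYP24A1, up to 8 genes with the largest increase and 8 with the largest decrease among called genes whose 3 calcitriol arrays all lay beyond their 3 DMSO arrays, and from each list the 2 called members with the largest change, or where none was called the member with the smallest p. For the difference between the lines and for the DMSO comparison it takes the 5 largest called genes in each direction, and for the latter ESR1, GATA3, VIM and CAV1 as well. A gene named outside this rule is said to have been chosen after its values were seen.

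Each result was recomputed with 1 choice changed at a time: replicate number as a block, each line fitted alone, an intensity trend with robust variance, array weights, quantile normalization repeated on the gene values, arrays centred on their median, the mean over probesets, all probesets of a gene, probesets above the 0.75 quantile of brightness (5.73 log2), brightness by the highest group mean, at least 1 probeset per gene, a change of at least 2-fold, probesets tested singly, the estimated correlation, and each of the 12 arrays left out in turn. After the data were seen, the 2 other scalings were also run without MDA-MB-231 DMSO replicate 1. Other splits of the arrays were tested as well.

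The fit was tested on simulated data for the same 16995 genes. With 50 genes per size of change, it recovered 82% of changes of 1 log2 unit in the MCF-7 comparison and 74% in the MDA-MB-231 comparison, 100% of changes of 2 log2 units in both, and 4% and 6% of changes of 0.5 log2. It made 10 false calls among 153 and 6 among 146. The simulated noise was independent between genes, with 1 spread per gene for all groups and no shift of whole arrays. These rates may therefore not hold on the real arrays, where such features are present. Depth is not counted on arrays, and precision is limited by the 3 arrays per group. Figures were drawn with Python 3.11.15, matplotlib 3.10.9, numpy 2.4.6 and pandas 2.3.3.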

Results

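The data were log2 expression values of 16995 genes on 12 exon arrays: 3 arrays each for calcitriol and DMSO in the cell lines labelled MCF-7, an estrogen receptor positive breast cancer line, and MDA-MB-231, an estrogen receptor negative one. The title of the series puts the question: whether calcitriol, the active hormone of vitamin D, brings on stress of the endoplasmic reticulum in such cells. The calcitriol dose and the DMSO percent of the controls went with the line, at 40 µM and 0.20% for MCF-7 and 50 µM and 0.25% for MDA-MB-231. The effects of line and dose therefore cannot be separated, and the DMSO percent of the calcitriol arrays is not labelled. Across genes, Pearson's r between arrays of 1 group ran from 0.946 to 0.975, and r between arrays of different lines ran from 0.748 to 0.810. The first principal component held 73.2% of the variance. The labels do not say whether the replicates were separate cultures, only that no technical replicates were made, so the p values measure the spread between these samples.

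The DMSO arrays of the lines were compared first, to check their labels and give the baseline. The arrays labelled MCF-7 had little of the luminal epithelial profile that the label MCF-7 implies, while the arrays labelled MDA-MB-231 were rich in mesenchymal and NF-kB genes. ESR1, the estrogen receptor, stood at 5.12 ± 0.25 log2 (SD, n = 3) in the arrays labelled MCF-7 and at 5.30 ± 0.21 in MDA-MB-231, a difference of 0.18 (SE 0.18, adjusted p = 0.466). GATA3, a luminal transcription factor, stood at 6.003 ± 0.197 and 6.44 ± 0.05 (adjusted p = 0.0833). Of the 18 luminal markers measured, 4 were higher in MDA-MB-231 and 3 lower, over all genes and adjusted over the list alone. The list as a whole was not called (median difference 0.25, adjusted p = 0.338), though by fry it was higher in MDA-MB-231 (adjusted p = 0.000149). Chosen after their values were seen, the keratin KRT8 stood at 6.76 log2 in the arrays labelled MCF-7 and 9.97 in MDA-MB-231, and the junction protein CDH1 at 4.57 and 4.37. They are therefore named by their label, as the arrays labelled MCF-7.

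Of the 16995 genes, 6022 differed between the lines in DMSO, 2863 of them higher and 3159 lower in MDA-MB-231. Highest above the arrays labelled MCF-7 were PLP2, a membrane proteolipid, by 7.76 log2 (SE 0.20, adjusted p = 1.07e-14), MMP1, a collagenase, by 7.36, GMFG, an actin regulator, by 7.05, SRGN, a proteoglycan core protein, by 6.36, and NT5E, an ectonucleotidase, by 6.30. Farthest the other way was SPP1 (osteopontin), at 12.48 ± 0.05 log2 in the arrays labelled MCF-7 and 3.23 ± 0.18 in MDA-MB-231, a difference of -9.25 (SE 0.18, adjusted p = 1.83e-16). It was followed by ALDH1A1, a retinaldehyde dehydrogenase, at -8.02, SCIN, an actin-severing protein, at -7.09, HAVCR1, a marker of kidney injury, at -6.80, and CYTIP, a cytohesin-binding protein, at -6.60. VIM (vimentin) was abundant in both lines, at 10.74 ± 0.25 and 11.51 ± 0.12 (adjusted p = 0.00383), and CAV1 (caveolin) was higher in MDA-MB-231, at 8.58 ± 0.37 against 6.52 ± 0.10 (adjusted p = 1.49e-06). VDR, the vitamin D receptor, was higher in MDA-MB-231, by 2.11 log2 (SE 0.23, adjusted p = 1.02e-06), against a low level of 4.58 log2 in the arrays labelled MCF-7. The lower level of MMP1, NT5E, SPP1, ALDH1A1, SCIN, HAVCR1 and CYTIP lay below the median of all probesets (3.82 log2), so the size and order of their differences rest on readings near background.

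Of the 21 lists, 5 were higher in MDA-MB-231 and 0 lower, where 8 had an unadjusted p under the threshold. Mesenchymal markers were higher at 18 of 20 members, 19 adjusted over the list alone (median 1.40 log2, adjusted p = 1.44e-14, and 0.031 with an estimated correlation). NF-kB inflammatory genes were higher at 16 of 18, 16 adjusted over the list alone (median 2.87, adjusted p = 8.20e-14, and 0.034 with an estimated correlation). The calls of the other 3 lists were lost with an estimated correlation (adjusted p = 0.351 for each). They were interferon-stimulated genes, with 12 of 19 members higher and 13 adjusted over the list alone, immediate early genes, with 12 of 17 and 13, and vitamin D receptor targets, with 12 of 26 higher and 2 lower by either count. The other 16 lists were not called (adjusted p from 0.0718 to 0.907), among them markers of fibroblasts, leukocytes and endothelium (median 0.13, adjusted p = 0.338). By fry the same 5 lists were called. So were luminal markers, apoptosis regulators, hypoxia and glycolysis genes and markers of other cell types as higher, and liver X receptor targets as lower (fry adjusted p from 0.000149 to 0.0224).

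**Figure D1:**
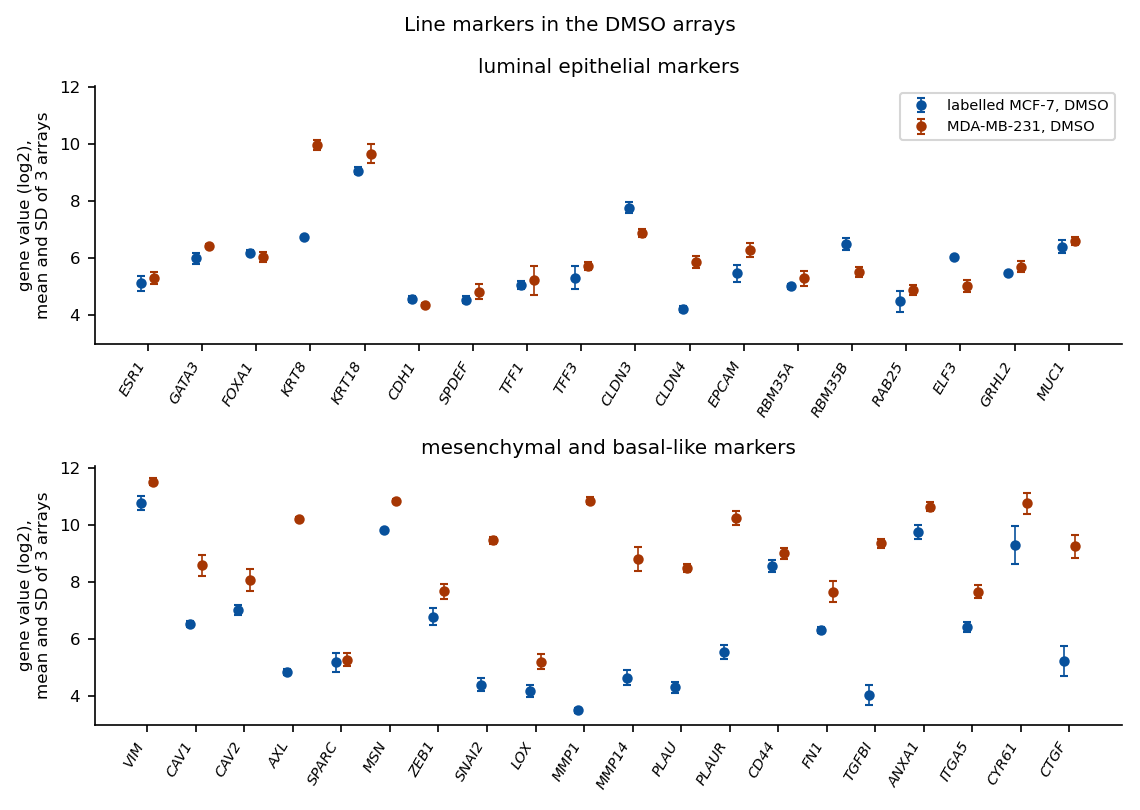
Log2 level of 18 luminal epithelial and 20 mesenchymal marker genes in the DMSO arrays of each line, with the mean of 3 arrays as a point and the SD as a bar. The mesenchymal markers have a median percentile among all genes of 94.8 in MDA-MB-231 and 39.9 in the arrays labelled MCF-7, and the luminal markers have median percentiles of 33.0 and 28.2.

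In the arrays labelled MCF-7, genes of the stress response that the kinase PERK and the transcription factor ATF4 control rose with calcitriol, and the vitamin D target CYP24A1 was not called. NUPR1, a stress-induced chromatin cofactor, rose 9.13-fold, from 6.72 ± 0.48 to 9.91 ± 0.40 log2 (SD, n = 3), by 3.19 (SE 0.32, adjusted p = 0.000186). HMOX1, the heme-degrading enzyme of the antioxidant response, rose 3.85-fold, from 7.61 ± 0.21 to 9.55 ± 0.14 (adjusted p = 0.0184). CHAC1, a glutathione-degrading enzyme and ATF4 target, rose 3.83-fold, by 1.94 (SE 0.34, adjusted p = 0.0214). MMP7, a secreted metalloprotease, fell 3.70-fold, from 6.76 ± 0.38 to 4.88 ± 0.43 (adjusted p = 0.00231).

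In all, 29 genes were called in the arrays labelled MCF-7, 21 higher and 8 lower with calcitriol, of which 26 changed at least 2-fold. SLFN5, of the interferon-inducible Schlafen family, rose by 2.19 log2 (SE 0.28, adjusted p = 0.00231), and UCA1, a long noncoding RNA, by 1.72 (SE 0.23, adjusted p = 0.00264). AKR1C2, a hydroxysteroid dehydrogenase with close paralogs that was read by 3 probesets, rose by 1.86 (adjusted p = 0.0178). BEX1, an adaptor protein, rose by 1.57 (adjusted p = 0.0214, but 0.75 and adjusted p = 0.611 with all probesets), CLGN, an endoplasmic reticulum chaperone of the testis, by 1.52 (adjusted p = 0.0232), and PMAIP1 (NOXA), a pro-apoptotic protein, by 1.43 (adjusted p = 0.00758). After MMP7, the largest decreases were those of SDPR, a protein of caveolae, at -1.55 (SE 0.21, adjusted p = 0.00264), CPS1, an enzyme of the urea cycle, at -1.32 (SE 0.19, adjusted p = 0.00504), and KLHL13, an adaptor of a ubiquitin ligase, at -1.14 (adjusted p = 0.011). The secreted proteases ADAMTS1 and ADAMTS15 fell by 1.02 and 1.00 (adjusted p = 0.0178 and 0.0497), the Golgi protein RAB30 by 0.91 (adjusted p = 0.039) and the cytoskeletal linker TLN2 by 0.83 (adjusted p = 0.0448). The fall of ADAMTS15 rested on the choice of probesets: it was -0.090 with all probesets (adjusted p = 0.989) or with brightness by the highest group mean (adjusted p = 0.977), and -0.42 with the mean over probesets (adjusted p = 0.383).

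CYP24A1, which encodes the enzyme that inactivates calcitriol and is a classic target of its receptor, was not called in the arrays labelled MCF-7. It went from 3.51 ± 0.32 to 4.18 ± 0.15 log2, an estimate of 0.68 (SE 0.22, adjusted p = 0.414) with 15 of 16 probesets higher. Over 23 alternatives the estimate ran from 0.50 to 1.22 and the adjusted p from 0.0472 to 0.868, and it was called in 1 of them, with the brightest probesets. Its level in DMSO lay below the median brightness of all probesets (3.82 log2). VDR stood at 4.58 ± 0.06 in DMSO and 4.43 ± 0.13 with calcitriol (-0.15, SE 0.23, adjusted p = 0.957). The 26 vitamin D receptor targets measured gave 0 calls, and 0 adjusted over the list alone (median 0.04, adjusted p = 0.435).

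Of the lists, 5 rose and 3 fell in the arrays labelled MCF-7 at the preset correlation, and only the PERK-ATF4 list kept its call with an estimated correlation. By fry it was likewise the only list called (adjusted p = 0.0213), with synthetases next (adjusted p = 0.0813). By the median of their members on each array, the calcitriol and DMSO arrays were separate for 3 of the 8 (PERK-ATF4 genes, synthetases and DNA replication and mitosis genes). They overlapped for the other 5. PERK-ATF4 genes had a median shift of 0.83 log2 (adjusted p = 7.48e-34, and 0.0415 with an estimated correlation), with 29 of 32 members positive, 5 called over all genes and 22 called adjusted over the list alone. The 5 were NUPR1, CHAC1, PCK2, a mitochondrial gluconeogenic enzyme, ALDH1L2, a mitochondrial folate enzyme, and PHGDH, which starts serine synthesis. Of these, PCK2 (1.39), ALDH1L2 (1.34) and PHGDH (1.25) were chosen after their values were seen. Of the transcription factors of the branch, also chosen after their values were seen, ATF4 gave 1.04 (SE 0.29, adjusted p = 0.273), DDIT3 (CHOP) 1.57 (SE 0.51, adjusted p = 0.42) and ATF3 0.25 (SE 0.27, adjusted p = 0.924). Aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, rose as a list (median 0.62, adjusted p = 4.56e-13, and adjusted p = 0.161 with an estimated correlation). None of the 13 was called over all genes, and 9 were called adjusted over the list alone. AARS, for alanine, gave 0.89 (adjusted p = 0.0821).

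The chaperone and degradation genes that ATF6 and XBP1 control were not called in the arrays labelled MCF-7. Of 38 measured, 12 were positive and 26 negative (median -0.07, adjusted p = 0.585), 0 were called, and 0 were called adjusted over the list alone. XBP1 itself gave 0.57 (adjusted p = 0.49), and the chaperone HSPA5 (BiP), chosen after its values were seen, gave -0.07 (adjusted p = 0.986). DNA replication and mitosis genes fell as a list, with 36 of 36 negative (median -0.41, adjusted p = 1.83e-15, and adjusted p = 0.334 with an estimated correlation). None of them was called over all genes and 12 were called adjusted over the list alone. The mitotic kinase PLK1 gave -0.96 (adjusted p = 0.0658), and MKI67, a proliferation marker chosen after its values were seen, gave -0.87.

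NRF2 antioxidant genes rose as a list in the arrays labelled MCF-7 (median 0.29, adjusted p = 1.74e-08, and adjusted p = 0.196 with an estimated correlation). HMOX1 was called, and 5 of 18 were called adjusted over the list alone. Cholesterol genes fell as a list (median -0.26, adjusted p = 0.00527, and adjusted p = 0.555 with an estimated correlation), with HMGCS1, an early enzyme of the pathway, at -0.84 (adjusted p = 0.109), 0 of 20 called and 1 called adjusted over the list alone. The call of that list was lost without DMSO replicate 2 (median -0.080, adjusted p = 0.139). The remaining called lists were near the threshold and were lost without single arrays and with an estimated correlation. Apoptosis regulators were called higher (median 0.03, adjusted p = 0.0218, and adjusted p = 0.523 with an estimated correlation), with PMAIP1 called and 2 called adjusted over the list alone. Their call was lost without calcitriol replicate 3 (adjusted p = 0.0835) or DMSO replicate 3 (0.141) and with all probesets (0.192). Hypoxia and glycolysis genes were called higher (median 0.15, adjusted p = 0.0166, and adjusted p = 0.555 with an estimated correlation) with 0 members called, 0 adjusted over the list alone and NDRG1, a stress-induced gene, at 0.93 (adjusted p = 0.335). Their call was lost without calcitriol replicate 2 (median 0.013, adjusted p = 0.140) or DMSO replicate 3 (median 0.053, adjusted p = 0.0632). Cytosolic heat shock genes were called lower (median -0.21, adjusted p = 0.0386, and adjusted p = 0.555 with an estimated correlation), with 0 members called, 0 adjusted over the list alone and SERPINH1, a collagen chaperone, at -0.45 (adjusted p = 0.735). Their call was lost when quantile normalization was repeated (0.182), with brightness by the highest group mean (0.0754) or at least 1 probeset per gene (0.0749), and without calcitriol replicate 1 (0.091) or 3 (0.117) or DMSO replicate 1 (0.0693) or 2 (0.382).

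The other 11 lists were not called in the arrays labelled MCF-7. Liver X receptor targets had a median of 0.16 (adjusted p = 0.435), with LPCAT3, a phospholipid acyltransferase, at -0.85 (adjusted p = 0.0952), and 1 member higher and 1 lower adjusted over the list alone. The p53 targets had a median of -0.01, a positive mean and a positive test direction (adjusted p = 0.103), with GDF15, a stress-induced cytokine, at 1.96 (adjusted p = 0.142) and 2 members higher adjusted over the list alone. Estrogen response genes had a median of -0.07 (adjusted p = 0.536), with STC2, a secreted glycoprotein, at 1.12 (adjusted p = 0.0875) as the 1 member called adjusted over the list alone. Both GDF15 and STC2 stand on the PERK-ATF4 list as well. Autophagy genes had a median of 0.06 and a mean of -0.02 (adjusted p = 0.958), with ATG5 at -0.42. NF-kB genes had 0.14 (adjusted p = 0.103), with IL8 at 0.69, interferon-stimulated genes 0.06 (0.492), with the RNA sensor DDX58 at 0.48, and immediate early genes 0.08 (0.242), with the phosphatase DUSP6 at 0.57. Ribosomal proteins had -0.03 with a positive test direction (0.942), with RPS9 at -0.50, luminal markers 0.02 (0.443), with EPCAM at -0.80, mesenchymal markers 0.06 with a negative mean and test direction (0.834), with CYR61 at -0.96, and markers of other cell types 0.02 (0.531), with KDR at 0.26. Lists with no count given here had 0 members called, over all genes and adjusted over the list alone.

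By the limma test, 1189 genes had an unadjusted p under the threshold in the arrays labelled MCF-7, 513 higher and 676 lower, and in 13.8% of genes the 3 calcitriol arrays all lay beyond the 3 DMSO arrays, where chance gives 10%. The 29 calls became 12 without calcitriol replicate 2, 13 without calcitriol replicate 3, 13 without DMSO replicate 1, 16 without DMSO replicate 2 and 11 without DMSO replicate 3, while array weights gave 81 and the mean over probesets 73. Of the called genes that the naming rule takes, NUPR1, SLFN5, UCA1, SDPR and CPS1 stayed called at the gene level in every alternative and with each array left out, as did MMP7 where it had a value (none with the brightest probesets). The other 11 lost their call in 2 to 16 of these, and probesets tested singly gave a call in 6 of the 29 genes.

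**Figure D2:**
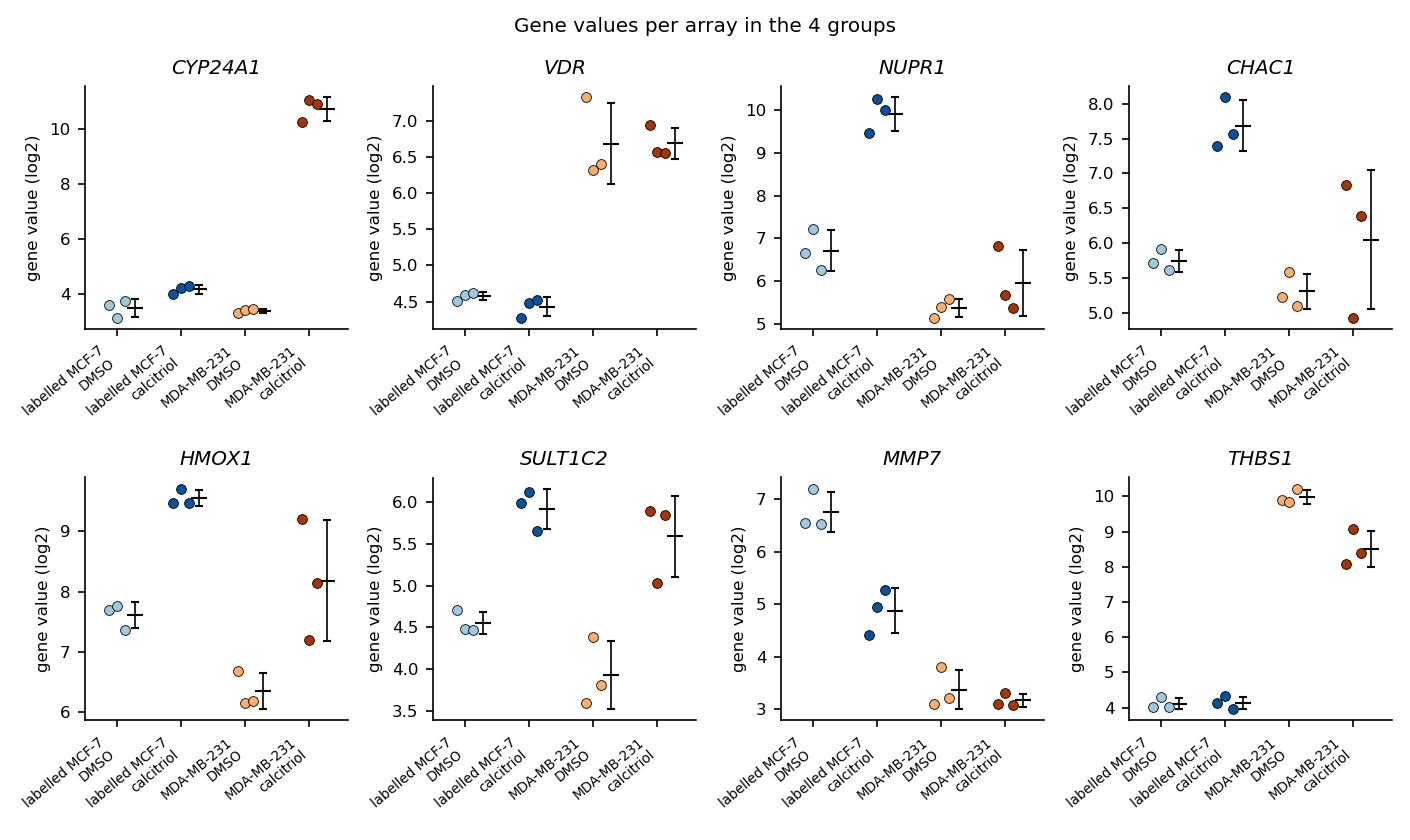
Log2 expression on each array (points) with the group mean and SD (bars, n = 3) for 8 genes in the 4 groups. CYP24A1 goes from 3.41 ± 0.08 to 10.72 ± 0.43 in MDA-MB-231 and from 3.51 ± 0.32 to 4.18 ± 0.15 in the arrays labelled MCF-7, and NUPR1 goes from 6.72 ± 0.48 to 9.91 ± 0.40 in the latter.

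In MDA-MB-231, the response was led by CYP24A1. It rose with calcitriol from 3.41 ± 0.08 to 10.72 ± 0.43 log2 (SD, n = 3), by 7.32 (SE 0.22, adjusted p = 4.36e-13). Its DMSO level lay below the median of all probesets (3.82 log2), so the size of the rise rests on a reading near background. GEM, a small GTP-binding protein, rose 5.41-fold, by 2.44 (SE 0.20, adjusted p = 5.17e-06), and EFTUD1, a GTPase of ribosome maturation, by 1.79 (SE 0.20, adjusted p = 0.000341). THBS1 (thrombospondin), a matrix glycoprotein, fell 2.77-fold, from 9.98 ± 0.21 to 8.51 ± 0.50, and SERPINB2, an inhibitor of plasminogen activators, fell 2.72-fold (adjusted p = 0.0143 for each).

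In all, 16 genes were called in MDA-MB-231, 14 higher and 2 lower, each by at least 2-fold. HMOX1 rose by 1.84 log2, from 6.34 ± 0.30 to 8.18 ± 1.00 (SE 0.33, adjusted p = 0.0382), a call lost in 13 of 23 alternatives, among them arrays centred on their median (adjusted p = 0.0539) and the line fitted alone (0.139). SULT1C2, a sulfotransferase, rose by 1.66 (SE 0.24, adjusted p = 0.0112), and CYP1A1, a monooxygenase induced through the aryl hydrocarbon receptor, by 1.58 (SE 0.25, adjusted p = 0.0143). G0S2, an inhibitor of fat breakdown on the list of vitamin D receptor targets, rose by 1.61 (adjusted p = 0.0266), and CLDN7, a tight junction protein, by 1.39 (adjusted p = 0.0287). VDR stood at 6.68 ± 0.56 log2 in DMSO and 6.69 ± 0.22 with calcitriol (adjusted p = 0.997). Of the transcription factors of the unfolded protein response, all chosen after their values were seen, ATF4 gave 0.31 (adjusted p = 0.768), ATF3 -0.012 (adjusted p = 0.993) and XBP1 0.27 (adjusted p = 0.685). DDIT3 gave 2.25 (SE 0.51, adjusted p = 0.0997), with calcitriol arrays at 10.10, 7.14 and 8.50 log2 and DMSO arrays at 7.32, 5.79 and 5.88.

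Of the lists, 7 rose and 3 fell in MDA-MB-231 at the preset correlation, and 0 kept their call with an estimated correlation. By fry only vitamin D receptor targets and liver X receptor targets were called, both higher (adjusted p = 0.0031 for each). By the median of their members on each array, the calcitriol and DMSO arrays were separate for 3 of the 10 (vitamin D receptor targets, cholesterol genes and liver X receptor targets). They overlapped for the other 7. Vitamin D receptor targets rose (median 0.24, adjusted p = 0.00012, and adjusted p = 0.304 with an estimated correlation), with 21 of 26 positive. CYP24A1 and G0S2 were called, and 7 were called adjusted over the list alone, among them, chosen after their values were seen, SERPINB1, a protease inhibitor, at 1.24, and THBD (thrombomodulin), at 0.74. PERK-ATF4 genes rose (median 0.44, adjusted p = 3.90e-06, and adjusted p = 0.371 with an estimated correlation), with 25 of 32 positive, 0 called over all genes and 10 called adjusted over the list alone. DDIT4, a stress-induced inhibitor of mTOR signalling, gave 2.15 (adjusted p = 0.063). ATF6-XBP1 chaperone and ERAD genes rose in this line (median 0.38, adjusted p = 2.90e-07, and adjusted p = 0.371 with an estimated correlation), with 35 of 38 positive, 0 called and 4 called adjusted over the list alone. Relative to the DMSO mean, the median of the members on calcitriol replicates 1, 2 and 3 was 0.56, 0.12 and 0.54 for PERK-ATF4 genes, against 0.22 on DMSO replicate 1, and 0.59, 0.072 and 0.39 for ATF6-XBP1 genes, against 0.17. SEC24D, a coat protein of vesicles that leave the endoplasmic reticulum, gave 0.95 (adjusted p = 0.129), and HSPA5, chosen after its values were seen, gave 0.75 (adjusted p = 0.362). Synthetases rose (median 0.32, adjusted p = 0.00267, and adjusted p = 0.462 with an estimated correlation), with YARS, for tyrosine, at 0.76 (adjusted p = 0.217), 0 of 13 called and 3 called adjusted over the list alone. The call of this list was lost without calcitriol replicate 3 (median 0.18, adjusted p = 0.0591) or DMSO replicate 2 (median 0.13, adjusted p = 0.174).

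Cholesterol genes rose in MDA-MB-231 with 20 of 20 positive (median 0.42, adjusted p = 2.65e-06, and adjusted p = 0.371 with an estimated correlation), 0 called and 6 called adjusted over the list alone. INSIG1, a sterol sensor, gave 1.29 (adjusted p = 0.0562). Liver X receptor targets rose (median 0.35, adjusted p = 0.0172, and adjusted p = 0.269 with an estimated correlation), with SCD, a fatty acid desaturase, at 0.84 (adjusted p = 0.124), 0 called and 2 called adjusted over the list alone, a call lost with all probesets (adjusted p = 0.0978) or brightness by the highest group mean (0.106) and without DMSO replicate 1 (0.0576). NRF2 antioxidant genes rose (median 0.31, adjusted p = 0.00168, and adjusted p = 0.412 with an estimated correlation), with HMOX1 called and 5 of 18 called adjusted over the list alone. NF-kB inflammatory genes fell, with 15 of 18 negative (median -0.41, adjusted p = 2.31e-08, and adjusted p = 0.246 with an estimated correlation), 0 called and 5 called adjusted over the list alone. Their median lay lower on DMSO replicate 2 (-0.32) than on calcitriol replicate 3 (-0.24). The chemokine IL8 gave -1.12 (adjusted p = 0.094). Mesenchymal markers fell as a list (median -0.16, adjusted p = 0.00263, and adjusted p = 0.371 with an estimated correlation), though the matrix enzyme LOX, at 0.87 (adjusted p = 0.128), was positive and the 1 member called adjusted over the list alone. DNA replication and mitosis genes were called lower (median -0.11, adjusted p = 0.000453, and adjusted p = 0.608 with an estimated correlation), with the helicase subunit MCM6 at -0.39 and 0 members called by either count. That call was lost without calcitriol replicate 1 (median 0.04, adjusted p = 0.417).

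The other 11 lists were not called in MDA-MB-231. Autophagy genes had a median of 0.19 (adjusted p = 0.0595), with WIPI1, of early autophagosomes, at 1.192 (adjusted p = 0.063) and 2 members called adjusted over the list alone. The p53 targets had 0.16 (0.288), with GDF15 at 2.03 (adjusted p = 0.104) as the 1 member called adjusted over the list alone, and hypoxia and glycolysis genes had 0.11 (0.513), with DDIT4 as the 1. Both GDF15 and DDIT4 stand on the PERK-ATF4 list as well. Interferon-stimulated genes had 0.29 (0.152), with IRF9 at 0.58, and apoptosis regulators 0.07 (0.679), with BIK at 0.92. Ribosomal proteins had -0.02 (0.152), with RPL10 at 0.28, and markers of other cell types -0.04 (0.152), with COL3A1 at -0.27. Medians were positive and test directions negative for estrogen response genes (0.06, adjusted p = 0.759, with PDZK1 at -0.54), immediate early genes (0.04, adjusted p = 0.722, with DUSP5 at 0.37) and luminal markers (0.04, adjusted p = 0.679, with GATA3 at 0.43). Heat shock genes had a median of -0.0040 and a mean above 0 (adjusted p = 0.679), with HSPB1 at 0.49. Lists with no count given here had 0 members called by either count.

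The MDA-MB-231 DMSO arrays differed among themselves. DMSO replicates 2 and 3 correlated at 0.946 with each other and at 0.930 to 0.959 with the calcitriol arrays, and their median gene values were 6.21 and 6.25 log2, against 6.41 to 6.45 on the other 4 arrays of the line. Over all probesets their medians were the higher ones, at 3.86 and 3.85 log2 against 3.79 to 3.81. DMSO replicate 1 correlated at 0.962 to 0.973 with the calcitriol arrays and at 0.956 to 0.958 with the other DMSO arrays, while its CYP24A1 level was 3.32 log2. By the limma test, 1728 genes had an unadjusted p under the threshold, 1328 higher and 400 lower, and in 12.5% of genes the 3 arrays of each group did not overlap, where chance gives 10%. The 16 calls became 158 without DMSO replicate 1, 78 without calcitriol replicate 2, 7 without DMSO replicate 2, 6 without calcitriol replicate 1, and 3 without DMSO replicate 3 or calcitriol replicate 3, and 6 when the line was fitted alone. Of the genes that the naming rule takes only CYP24A1, EFTUD1 and, where it had a value (none with the brightest probesets), GEM stayed called in every alternative at the gene level, while probesets tested singly gave a call in 5 of the 16 genes. The lean to higher values depended on the scaling: 14 of the 16 calls were higher as deposited, 24 of 30 with quantile normalization repeated and 10 of 14 with arrays centred, where the unadjusted genes split into 708 higher and 1073 lower.

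**Figure D3:**
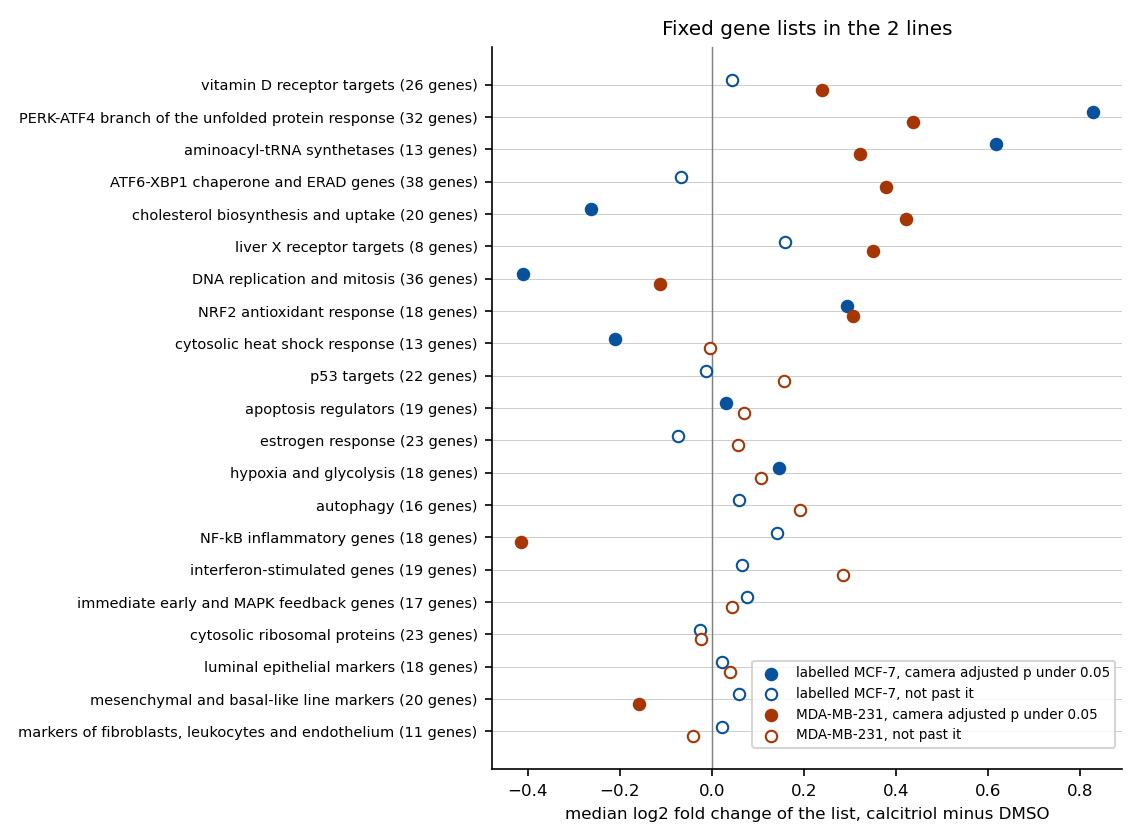
Median log2 change with calcitriol over the measured members of each of the 21 gene lists, for the arrays labelled MCF-7 and for MDA-MB-231, with filled points for lists called by camera at the preset correlation. The PERK-ATF4 list lies at 0.83 in the arrays labelled MCF-7 and at 0.44 in MDA-MB-231, and the ATF6-XBP1 list at -0.07 and 0.38.

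The lines were compared to ask whether they respond alike. They shared 3 genes that rose with calcitriol, CYP1A1, HMOX1 and SULT1C2, where independent lists would share 0.0173 (Fisher's exact p = 5.87e-07), and 0 genes fell in both. Both sets of calls rest on 1 fit whose spread per gene is shared by the lines. They are thus not independent by construction, and that p value takes no account of it. With each line fitted alone, 0 genes were shared. Across the 16995 genes, the effects in the lines correlated weakly (Pearson r = 0.160, Spearman rho = 0.130, genes not being independent replicates). Of the 29 genes called in the arrays labelled MCF-7, 21 had the same sign in MDA-MB-231, as did 9 of the 16 called in MDA-MB-231 the other way round. The effect of calcitriol differed between the lines at 8 genes by the test of the difference itself, MDA-MB-231 minus MCF-7. CYP24A1 differed by 6.64 log2 (SE 0.31, adjusted p = 8.48e-10) and GEM by 3.06 (SE 0.28, adjusted p = 3.27e-05). HSPB8, a small heat shock protein, differed by 1.88 (adjusted p = 0.0412), SDPR by 1.82 (adjusted p = 0.0386) and EFTUD1 by 1.61 (adjusted p = 0.0477). In the other direction were NUPR1 at -2.60 (SE 0.45, adjusted p = 0.0463), PMAIP1 at -1.84 (SE 0.31, adjusted p = 0.0412) and ALDH1L2 at -1.67 (SE 0.24, adjusted p = 0.0127).

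The effect also differed between the lines for 7 of the 21 lists at the preset correlation, and for 0 with an estimated one or by fry (lowest fry adjusted p = 0.0821). Relative to the arrays labelled MCF-7, the effect in MDA-MB-231 was higher for cholesterol genes (median difference 0.58, adjusted p = 4.69e-09, and adjusted p = 0.432 with an estimated correlation), ATF6-XBP1 genes (0.45, 7.21e-06, and 0.484), vitamin D receptor targets (0.32, 0.00332, and 0.484) and DNA replication and mitosis genes (0.32, 0.0025, and 0.679). It was lower for NF-kB genes (-0.46, 5.10e-09, and 0.222), PERK-ATF4 genes (-0.29, 5.89e-08, and 0.484) and synthetases (-0.26, 0.0025, and 0.484). The PERK-ATF4 members did not all go this way: the estimate was lower in MDA-MB-231 for 22 of 32 and higher for 10. Among the 10, chosen after their values were seen, were DDIT3 (2.25 against 1.57 in the arrays labelled MCF-7) and DDIT4 (2.15 against 0.95). Neither difference was called. NUPR1 and ALDH1L2 were the PERK-ATF4 members called, with 4 called adjusted over the list alone, and adjusted over the list alone 5 cholesterol genes were called higher and 1 NF-kB gene lower. CYP24A1 was the 1 vitamin D receptor target called by either count, and 0 members were called by either count in the other 3 lists. The call of DNA replication and mitosis genes was lost without DMSO replicate 2 of the arrays labelled MCF-7 (median difference 0.18, adjusted p = 0.0592). It was also lost without calcitriol replicate 2 (0.29, adjusted p = 0.0800) or DMSO replicate 2 (0.18, adjusted p = 0.0999) of MDA-MB-231. That of synthetases was lost without MDA-MB-231 calcitriol replicate 2 (-0.13, adjusted p = 0.0985).

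By the limma test of the difference, 1185 genes had an unadjusted p under the threshold, 865 higher and 320 lower as deposited, against 633 and 581 with quantile normalization repeated and 491 and 728 with arrays centred. The lean to higher values thus depended on the scaling. The median over all genes was 0.10 as deposited and -0.03 with arrays centred, where 6 of 13 calls were higher in place of 5 of 8. The 8 calls became 3 without any of calcitriol replicate 3 or DMSO replicate 1 of the arrays labelled MCF-7 or calcitriol replicate 3, DMSO replicate 2 or DMSO replicate 3 of MDA-MB-231, 4 without calcitriol replicate 2 or DMSO replicate 2 of the arrays labelled MCF-7, and 5 without their calcitriol replicate 1 or DMSO replicate 3, and the 3 shared genes became 0 to 11 with an array left out. CYP24A1, ALDH1L2 and, where it had a value (none with the brightest probesets), GEM stayed called at the gene level in every alternative and with each array left out. The other 5 lost their call in 13 to 15 of these, and probesets tested singly gave a call in 2 of the 8 genes.

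**Figure D4:**
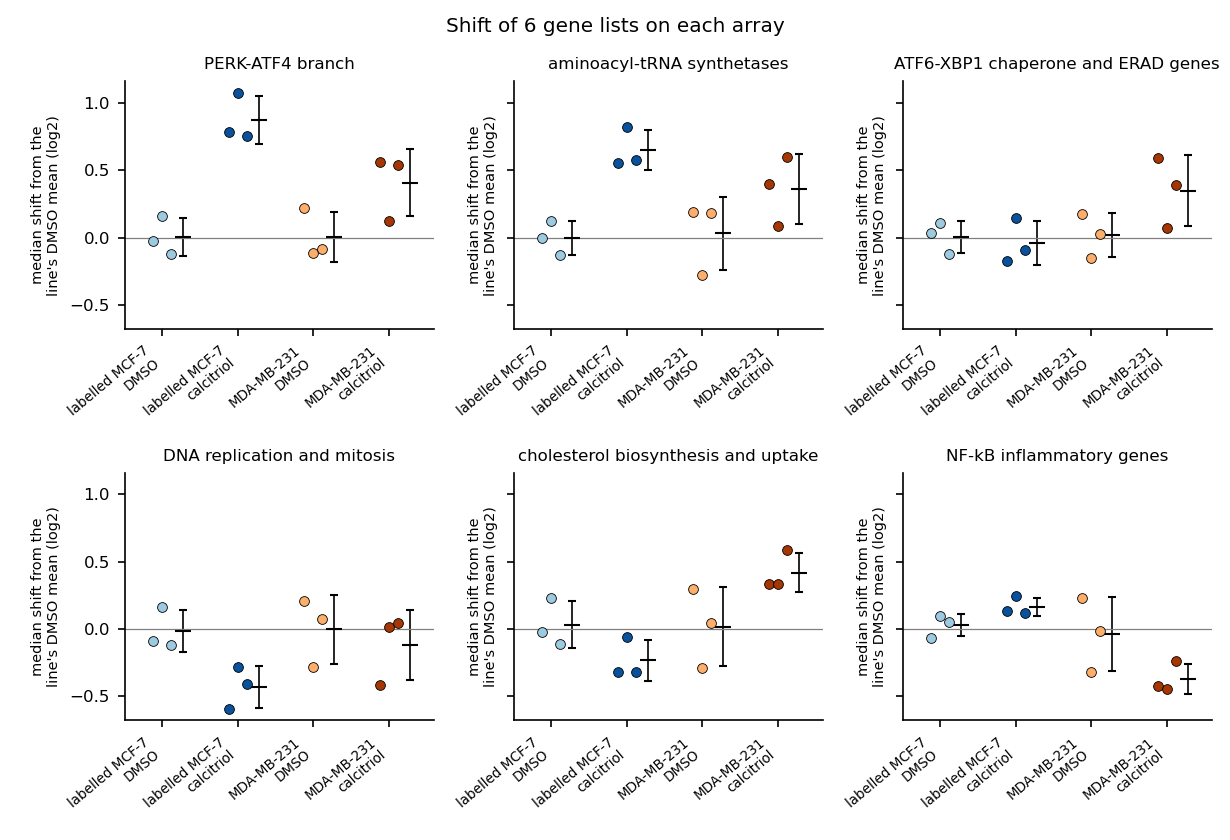
Median shift, in log2, of the members of 6 gene lists on each array from the DMSO mean of its line. The calcitriol arrays labelled MCF-7 lie at 0.75 to 1.08 for PERK-ATF4 genes, against -0.12 to 0.16 on their DMSO arrays, while MDA-MB-231 calcitriol arrays lie at 0.12 to 0.56, against -0.12 to 0.22.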

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

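The tests of exchanged labels, of admixed MDA-MB-231 RNA and of an amino acid type of response were chosen after their results were seen. So were the tests of the 3 explanations for the CYP24A1 difference and the rescaling of the splits that gave 65 and 36 calls. The other tests were chosen before. However, the readings of the luminal marker count and of the splits for shared genes each use a condition beyond the rule chosen before. By that rule alone, the luminal count met the number set for probesets that do not report. The share of splits with as many shared genes lay under 0.05, which that rule took to exclude chance.

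The arrays labelled MCF-7 had little of a luminal epithelial profile, with ESR1 at 5.12 log2, KRT8 at 6.76 and CDH1 at 4.57 in DMSO, though KRT18 stood at 9.07 and CLDN3 at 7.78. Exchange of the labels of the lines is argued against by the mesenchymal markers, whose median was 1.40 log2 higher in the arrays labelled MDA-MB-231. An exchange needs it lower. A large share of MDA-MB-231 RNA in the other arrays is argued against by 29 genes above 9 log2 in MDA-MB-231 that lay over 4 log2 lower there. A small share could leave such differences in place, and the test does not exclude it. RNA of another line also stays open. For part of the luminal markers it stays open that their probesets may not report on these arrays. Of the 18, 7 differed between the lines past the threshold, KRT8 with 9.97 in MDA-MB-231, so these do report. For the rest the count of 3 markers in the upper range of gene values (7.36 log2) decides nothing, since the pattern itself keeps it low. For RNA of an epithelial line of the PAX8-positive Müllerian or renal kind, 4 of the 10 measured genes of a 12-gene list were higher in the arrays labelled MCF-7 and 0 lower: PAX8 at 8.47 against 5.79 log2, FOLR1 at 7.84 against 5.11, PAX2 at 7.51 against 6.15 and SOX17 at 7.04 against 6.54. These 4 were too few for the count that the test asked for and too many to exclude it, so this hypothesis and a variant of MCF-7 with other markers cannot be told apart.

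PERK-ATF4 genes rose in the arrays labelled MCF-7 and the ATF6-XBP1 chaperone list was not called. Array scaling is argued against, because at least 101% of the median shift was left under the 2 other scalings, and so is the brightness of these genes, because 0% of 10000 random lists matched for level reached the shift (highest 0.15 against 0.83). A shift carried by 1 array is argued against as well, because at least 91.1% of it was left without any 1 of the 6 arrays. An amino acid type of response, with serine synthesis and tRNA charging genes and without chaperones, is a candidate explanation: the chaperone median was -0.068 and that of the synthetases 0.62, a list whose call was lost with an estimated correlation (adjusted p = 0.161). It was tested on the data it was found in and stays a hypothesis. The chaperone result is part of the pattern itself. Genes of serine synthesis and tRNA charging were taken as ATF4 targets, and PHGDH stands on the PERK-ATF4 list. These values therefore cannot tell an amino acid type of response from one through PERK. The dose, the line and the identity of the arrays stay among the untested explanations.

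The estimated rise of CYP24A1 was 6.64 log2 larger in MDA-MB-231 than in the arrays labelled MCF-7, from DMSO levels of 3.41 and 3.51 log2 that both lay below the median of all probesets (3.82), so its size rests on readings near background. A few faulty probesets are argued against by 82.4% of its probesets, which rose by over 4 log2 in MDA-MB-231 and by under 2 in the other arrays. They were 14 of all 17 probesets, and 16 of the 17 passed the brightness floor and entered the gene value. On the absence of active compound in the cultures labelled MCF-7, 3 genes rose in both lines (CYP1A1, HMOX1 and SULT1C2), against 0.0173 for independent lists. That count cannot decide the question. The number it had to reach was set after it was seen. It was 0 with each line fitted alone and ran from 0 to 11 with an array left out. A lower level of the receptor transcript in the arrays labelled MCF-7 is a candidate explanation, since VDR stood at 4.58 ± 0.06 log2 there and 6.68 ± 0.56 in MDA-MB-231 in DMSO, a difference of 2.11 against a low reading. Receptor protein was not measured, and the dose and the identity of the arrays stay open, as untested explanations.

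The test of the difference between the lines also called GEM (3.06 log2), HSPB8 (1.88), SDPR (1.82), EFTUD1 (1.61), ALDH1L2 (-1.67), PMAIP1 (-1.84) and NUPR1 (-2.60). For gene lists it called cholesterol genes (median difference 0.58), ATF6-XBP1 genes (0.45), vitamin D receptor targets (0.32), DNA replication and mitosis genes (0.32), synthetases (-0.26), PERK-ATF4 genes (-0.29) and NF-kB genes (-0.46), each lost with an estimated correlation.

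Among 436932 probesets that named no gene and lay above the brightness floor, outside the gene comparisons, 2 were called with calcitriol in the arrays labelled MCF-7, both higher, and 8 in MDA-MB-231, 7 higher and 1 lower. By an unadjusted p under the threshold the numbers were 25078 and 37046. The largest was probeset 3889749 in MDA-MB-231, at 7.70 log2 (SE 0.26, adjusted p = 1.97e-08), and in the arrays labelled MCF-7 it was probeset 3403842, at 2.36 (SE 0.23, adjusted p = 0.0354).

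With 3 arrays against 3, the 10 possible splits cannot give a share under 0.05. The real split gave 29 genes in the arrays labelled MCF-7 and the highest other split gave 1, and in MDA-MB-231 the numbers were 16 and 1. For lists they were 8 and 6 in the arrays labelled MCF-7 and 10 and 7 in MDA-MB-231, and for genes between the lines in DMSO 6022 and 0. Of 100 splits drawn for the genes whose response differed between the lines, 3 gave as many as the real 8. They were the real split and those with 65 and 36 calls. That share lies under 0.05, but it does not exclude chance, since other groupings of the arrays gave far more calls. Many drawn splits also kept the real groups of 1 line, in the real or the exchanged order, so they were not free of the calcitriol effect. For the 7 lists that differed between the lines, 18 of 100 splits gave as many (highest other 11), so chance is not excluded. For the 3 genes that rose in both lines, 1 of 100 splits, the real one, gave as many (highest other 0), but no other split called enough genes in both lines to share more than 1, so chance cannot be told apart by this count. The splits with 65 and 36 calls point to a structure of the samples. Both set calcitriol replicates 1 and 3 with DMSO replicate 1 against the rest in MDA-MB-231, and in the arrays labelled MCF-7 they set calcitriol replicate 1 and DMSO replicate 3 with calcitriol replicate 3 and with DMSO replicate 1 respectively. Each fell to 1 call when quantile normalization was repeated and to 1 when arrays were centred, where the real split gave 11 and 13, and the MDA-MB-231 arrays set together had median gene values of 6.41 to 6.45 log2 against 6.21 to 6.41 for the other 3.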

How the results depend on the processing

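The alternatives were all chosen before the data were examined, except that the other scalings without MDA-MB-231 DMSO replicate 1 were chosen after seeing the data: quantile normalization then gave 123 genes in MDA-MB-231 and centring 75. In the results that follow, the cause of a change was not tested except where stated. Among genes that were called, 435 of 490 values under another setting kept their direction and their side of the threshold, as did 421 of 564 with an array left out, and the rest kept their direction but lost the call. Among called lists 312 of 318 and 343 of 360 did so, with the estimated correlation set apart for all lists. Among genes not called, 392 of 438 values did so under another setting, 38 passed the threshold and 8 turned, and among lists not called the numbers were 250 of 274, 11 and 13. The totals for called genes and lists hold the named genes and the lists called between the lines in DMSO. Each of these kept its call throughout, so the calcitriol calls and those for the difference between the lines held less often than the totals say. The PERK-ATF4 list kept its call in the arrays labelled MCF-7 in all 24 alternatives, with medians of 0.65 to 0.90 and an adjusted p of 0.0415 with the estimated correlation. Depth is not counted on arrays: genes near the brightness floor, such as CYP24A1 and VDR in the arrays labelled MCF-7, are read with little signal over background.

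Replicate number as a block gave 44 genes in the arrays labelled MCF-7, 84 in MDA-MB-231, 15 that differed between the lines and 11 that changed in the same direction in both. Whether the numbers pair the arrays is not settled. For arrays with the same number, r between the changes from the group mean was -0.175, 0.0725 and 0.0668 in the arrays labelled MCF-7. In MDA-MB-231 it was -0.0104, 0.0910 and 0.131. For arrays with different numbers it ran from -0.221 to 0.175 and from -0.288 to 0.176. A pairing that the main fit leaves out is thus not excluded.

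With each line fitted alone on its own 6 arrays, MDA-MB-231 gave 6 genes, 5 of them among its 16 calls. The arrays labelled MCF-7 gave 36 on as many arrays, 22 of them among their 29 calls, and 0 genes were shared between the lines. The main fit, by contrast, uses 1 spread per gene for both lines. Array weights gave 81 genes in the arrays labelled MCF-7. Quantile normalization repeated gave 30 in MDA-MB-231, and centred arrays gave 13 that differed between the lines. The mean over probesets gave 73 genes in the arrays labelled MCF-7, 64 in MDA-MB-231, 22 that differed, 5 shared and r = 0.222. All probesets gave 3 that differed and 1 shared, at least 1 probeset per gene gave 3 that differed, the brightest probesets gave r = 0.215, and brightness by the highest group mean gave 28 genes in MDA-MB-231 and 4 that differed. Probesets tested singly gave 24 in the arrays labelled MCF-7, 44 in MDA-MB-231 and 23 that differed, a count of another unit. A change of at least 2-fold left 2786 genes between the lines in DMSO, by its construction. The brightest probesets gave no value for MMP7, AKR1C2, BEX1, ADAMTS15, GEM and HSPB8, which kept too few. The estimated correlation left 1 of 8 called lists in the arrays labelled MCF-7, 0 of 10 in MDA-MB-231, 0 of 7 for the difference and 2 of 5 between the lines in DMSO. Of the genes that lost a call, ADAMTS15 became -0.090 with all probesets and with brightness by group and -0.42 with the mean, and BEX1 became 0.75 with all probesets.

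By the sign of a gene's estimate or the direction of a list's test, only results that were not called turned. The VDR estimate in MDA-MB-231, near 0, became -0.013 with array weights, -0.10 with quantile normalization and -0.12 with centring. With all probesets VDR in the arrays labelled MCF-7 became 0.041, GATA3 in MDA-MB-231 -0.029, COL3A1 there 0.028 and ESR1 between the lines -0.026, and with the brightest probesets KDR in the arrays labelled MCF-7 became -0.14. For lists the direction of the test turned, with these medians. In the arrays labelled MCF-7 they were ATF6-XBP1 genes at -0.0011 with quantile normalization, ribosomal proteins at -0.023 with the mean over probesets, estrogen response genes at 0.0012 with all probesets, interferon-stimulated genes at -0.095 with the brightest probesets, and autophagy genes at 0.060 with brightness by group and with at least 1 probeset. In MDA-MB-231 they were heat shock genes at -0.040 with quantile normalization, immediate early genes at 0.16 with the mean and 0.14 with the brightest probesets, and luminal markers at 0.077 with the mean, 0.12 with all probesets, 0.085 with brightness by group and 0.062 with at least 1 probeset.

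With each array left out in turn, the calls ran from 11 (without DMSO replicate 3) to 34 in the arrays labelled MCF-7, from 3 (without DMSO replicate 3 or calcitriol replicate 3) to 158 (without DMSO replicate 1) in MDA-MB-231, from 3 to 7 for the difference between the lines and from 0 to 11 (without MDA-MB-231 calcitriol replicate 2) for shared genes. The correlation across genes ran from 0.0820 (without MDA-MB-231 calcitriol replicate 1) to 0.206 (without DMSO replicate 2). VDR in MDA-MB-231 ran from -0.18 to 0.32. The list medians ran, in the arrays labelled MCF-7, from -0.17 to 0.014 for ATF6-XBP1 genes, from -0.12 to 0.10 for vitamin D receptor targets, from -0.038 to 0.13 for autophagy genes, from -0.091 to 0.072 for ribosomal proteins and from -0.025 to 0.062 for markers of other cell types. In MDA-MB-231 they ran from 0.076 to 0.46 for interferon-stimulated genes, from -0.0031 to 0.094 for estrogen response genes, from -0.057 to 0.22 for immediate early genes and from -0.14 to 0.12 for heat shock genes.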

Other observations

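The genes in this part were chosen after their values were seen, while leaving out each array in turn was planned.

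The arrays labelled MCF-7 had 12 further called genes, each higher with calcitriol by 2.03 to 2.62-fold. They held 3 mitochondrial or serine pathway enzymes of the PERK-ATF4 list, PCK2 (1.39 log2), ALDH1L2 (1.34) and PHGDH (1.25), and SLC1A4, a transporter of neutral amino acids (1.18, adjusted p = 0.0184). TUBE1, a tubulin, rose by 1.38 (adjusted p = 0.0256), GPR56, an adhesion receptor, by 1.31 (adjusted p = 0.00504), GCNT3, a mucin glycosyltransferase, by 1.31 (adjusted p = 0.0184), ULBP1, a stress ligand of natural killer cells, by 1.25 (adjusted p = 0.0417), PDK4, a kinase of pyruvate dehydrogenase, by 1.192 (adjusted p = 0.0314), and CTAGE5, a protein of collagen export, by 1.02 (adjusted p = 0.0451). CYP1A1 (1.38) and SULT1C2 (1.37) completed the 12. MDA-MB-231 had 6 further called genes, higher by 2.03 to 2.53-fold: ZNF165, a zinc finger protein (1.34), RGS5, a regulator of G protein signalling (1.32), NUDT7, a peroxisomal hydrolase (1.26), EPAS1, a hypoxia-inducible transcription factor (1.18), LIPG, an endothelial lipase (1.14), and RUNDC2A (1.02). None of these 6 was called in the arrays labelled MCF-7, but their difference between the lines was not called either.

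Without DMSO replicate 1, the MDA-MB-231 comparison gave 158 genes, 132 higher and 26 lower, in place of 16, and it held 16 of the 16. The lean to higher values went with the lower median gene values of the DMSO arrays left (6.21 and 6.25 log2, against 6.41 to 6.45 on the calcitriol arrays). Over all probesets the order was reversed, with medians of 3.86 and 3.85 log2 on these DMSO arrays against 3.79 to 3.81 on the calcitriol arrays. Quantile normalization repeated gave 123 genes, 69 higher and 54 lower, and centred arrays 75, 34 higher and 41 lower, both chosen after seeing the data. Of the PERK-ATF4 list, 4 were called as deposited: DDIT3 (2.75 log2), DDIT4 (2.72), ASNS, which makes asparagine (2.43), and PCK2. INSIG1 and SC4MOL of the cholesterol list were called, and CLMN and SERPINB1 joined CYP24A1 and G0S2 among vitamin D receptor targets. Of these newly called genes, DDIT3, DDIT4 and INSIG1 kept the call under both scalings, SC4MOL and SERPINB1 lost it with centred arrays (adjusted p = 0.0578 and 0.0699), and ASNS, PCK2 and CLMN lost it under both. The largest decreases as deposited were those of HORMAD1 (-1.87), ANKRD30B (-1.71) and C6orf10 (-1.70), which stand on none of the lists. Without DMSO replicate 2 or 3, the comparison gave 7 and 3 genes. With 2 DMSO arrays left, the spread rests on the other groups as well, and these 158 genes were singled out after their number was seen.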
